A study of Mus musculus with 2 samples.

How the data were processed

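Tissue of the retinal pigment epithelium (RPE) and choroid was profiled by droplet single-cell RNA sequencing in 2 mouse libraries, 1 per genotype. The Tsc1 flox library came from mice with a conditional Tsc1 allele and no Cre, and the Tsc1 RPE KO library from mice that also carried the Best-Cre transgene, which the labels describe as RPE-specific. Each library pooled tissue of 1 male and 1 female aged 10 weeks, per the labels. The neural retina was removed, the tissue was digested with enzymes and live cells were sorted before loading, per the labels' protocols.

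The deposited values are raw UMI counts (unique molecular identifiers, 1 per captured RNA molecule) per gene and barcode, with no filter on barcodes. The submitters' processing notes name Cell Ranger 2.1.1 and the mouse build mm10, while the header of the deposited count matrices names Cell Ranger 4. The labels describe a 3' v2 kit, and the deposited barcode lists of both libraries together held 1207754 distinct barcodes, more than the barcode list of that kit holds. Which program version and kit gave the counts is therefore open. The gene list held 32285 genes, of which 32158 had their identifier in the GENCODE M21 annotation of the same genome build, which gave the coordinates printed here. The count matrices held 10771118 UMIs on 661479 listed barcodes for Tsc1 flox and 12574364 UMIs on 728310 listed barcodes for Tsc1 RPE KO.

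Barcodes were called as cells from at least 10% of the 99th percentile of the UMI counts of the top 3000 barcodes in each library, and at least 500, which gave minimums of 1487.4 UMIs for Tsc1 flox and 1373.6 UMIs for Tsc1 RPE KO. Of 1587 and 1940 barcodes above these minimums, 55 and 68 with fewer than 200 genes were left out. Erythroid markers made up 97.8% and 98.0% of the UMIs of those barcodes. The limit of 20% mitochondrial UMIs removed 0 barcodes in each library. Scrublet, as run in scanpy 1.11.5, marked 8 and 19 barcodes as doublets, which were removed, leaving 1524 and 1853 cells. Counts were scaled per cell and log-transformed, the 2000 most variable genes were reduced to 30 principal components, and a shared-neighbour graph over 20 neighbours was clustered with leidenalg 0.10.2 at resolution 1. This gave 16 clusters.

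Clusters were named from marker lists that were fixed before the data were examined. A cluster took the name of its leading class only when at least 3 markers were each seen in 10% of its cells and stood at least 2-fold above the other clusters, when its 10 leading genes held no more markers of another class than of its own, and when its markers averaged more than 1 on the log2 scale above the other clusters. The last condition was raised from 0 to 1 after the clusters had been seen, and it alone kept cluster 4, with 26 and 248 cells, from the macrophage name. Clusters 3, 5 and 12 stayed unnamed because fewer than 3 markers of their leading class passed. With the limit at 0 the macrophage class would have held clusters 4 and 8. Names ending in "-like" refer to these rebuilt classes.

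With 1 library per genotype there was no test between genotypes, and no p-value is given. Counts were summed over the cells of a class in each library and expressed per 1000000 UMIs of that class (CPM). Intervals are exact 95% Poisson intervals for CPM, exact conditional binomial intervals for the ratio of 2 sums and exact Clopper-Pearson intervals for shares of cells. They cover counting error only, not differences between cells, mice, pools or preparations. A gene with 0 UMIs in 1 library was given a ratio against a floor of 3 counts summed over that library's cells of the class. A gene counted as measured in a class with at least 50 UMIs over both libraries. For each of 22 gene lists, fixed before the data were examined, the median log2 ratio of measured members was placed among 10000 random lists of the same size matched on mean expression, when at least 3 members were measured. Its counting interval came from 1000 Poisson redraws. Of the list entries, 3 symbols (Aldoa, Ctgf and Ddit3) had no row of that name and were not measured.

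The genes named in the text followed a rule fixed before the data were examined. It took Ppp1r1b and Tsc1, up to 4 members of each list, the 12 genes with the highest and the 12 with the lowest ratio in RPE-like cells, and 4 in each direction in every other named class with at least 50 cells per library, all ranked by the bound of the 95% interval nearest to a ratio of 1. The ranked genes left out markers of other classes, mitochondrially encoded genes, Xist, Tsix and Y-linked genes, and genes more abundant in free RNA than in the class. Genes named outside this rule are said to be chosen after their values were seen.

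Free RNA was profiled from barcodes with 10 to 100 UMIs. Shares of cells with a UMI of a gene were also given after each cell had been thinned to 1000 UMIs; 0 cells lay below that depth. RPE-like barcodes with at least 10 UMIs of B cell, T or NK cell, macrophage, mast cell and neutrophil markers together were called mixed barcodes, a definition set after the data had been seen. After a first look at the alternatives, the direction of a gene at 0 UMIs was read from its CPM, and genes with at most 3 UMIs in both libraries were given no ratio there. Alternatives covered the cell calling, the doublet and mitochondrial filters, the clustering, the scaling, the weight of each cell, free RNA, the minimum count and the matching of random lists.

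The ratio and list calculations were tested on simulated Poisson counts with the RPE-like totals of both libraries and 200 genes changed. Such counts hold no spread between cells and follow the model behind the intervals. The cover of the intervals therefore checks the calculation only, not whether they fit the real cells. Of 376 measured simulated genes, the intervals held the true ratio for 95.7% of 231 unchanged genes. The interval lay on the true side of 1 for 100% of genes changed 4-fold upwards, 82% of those changed 2-fold upwards and 70.4% of those changed 2-fold downwards. A simulated list of 20 genes raised together lay at percentile 100, and an unchanged list of 19 genes at percentile 75.6. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.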

Results

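Single cells of RPE and choroid from mice with a floxed Tsc1 gene were compared with those from mice in which Cre removes Tsc1 in the RPE. Tsc1 encodes a subunit of the complex that restrains the kinase mTORC1, and the series title names DARPP32, the product of Ppp1r1b, as a target of hyperactive mTORC1. The Tsc1 flox library gave 1524 cells with a median of 4525 UMIs and 1749 genes per cell, and the Tsc1 RPE KO library 1853 cells with a median of 4617 UMIs and 1790 genes. Each genotype was 1 library of 2 pooled mice, so the differences below have no replicate check and the intervals cover counting error only.

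Immune cells made up most of both libraries, and the RPE was rare in each. RPE-like cells, led by Ttr, Ptgds, Rgr, Rdh5 and Rpe65, were 12 of 1524 cells in Tsc1 flox (0.787%, 95% exact interval 0.408 to 1.37%) and 48 of 1853 in Tsc1 RPE KO (2.59%, 1.92 to 3.42%). Rod-like cells were 2.76% (1.99 to 3.71%) in Tsc1 flox and 9.50% (8.20 to 10.9%) in Tsc1 RPE KO, although the neural retina had been removed. B cell-like cells were 27.0% (24.8 to 29.3%) and 17.2% (15.5 to 19.0%), fibroblast-like cells 17.4% (15.5 to 19.4%) and 9.61% (8.30 to 11.04%), T or NK cell-like cells 22.0% (19.9 to 24.1%) and 19.6% (17.8 to 21.5%), and macrophage-like cells 6.76% (5.55 to 8.14%) and 5.88% (4.85 to 7.05%). The macrophage share turned to 8.46% (7.12 to 9.98%) and 19.3% (17.5 to 21.1%) when cluster 4 was counted with the class, as a limit on names did before it was raised after seeing the clusters, so no direction is given for it. Endothelial-like cells, marked by Plvap, Egfl7 and Cldn5, had 2.69% (1.94 to 3.63%) and 2.64% (1.96 to 3.48%).

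The widest gap in composition lay in a pair of unnamed clusters that shared Treml4, Ace, Csf1r and Nr4a1. Cluster 4, led by Cd300e, Fabp4 and Fcgr4, held 1.71% (1.12 to 2.49%) of Tsc1 flox and 13.4% (11.9 to 15.0%) of Tsc1 RPE KO cells, and cluster 5, led by S100a9, S100a8, Eno3 and Treml4, held 3.94% (3.02 to 5.04%) and 10.6% (9.21 to 12.1%). Cluster 3, led by the natural killer cell genes Klra4, Gzma and Ncr1, held 11.2% (9.68 to 12.9%) and 6.58% (5.50 to 7.81%). It lay outside the T or NK cell-like class, whose share above therefore leaves these cells out. Cluster 12, led by Siglech, held 1.31% (0.803 to 2.02%) and 1.03% (0.618 to 1.60%). Digestion, the live-cell sort and the UMI minimum can set all of these shares, and a cluster drawn mostly from 1 library, as cluster 4 is, may reflect that library. With at least 1000 UMIs in both libraries the RPE-like share of Tsc1 flox was 1.40% against 3.37% in Tsc1 RPE KO, and with at least 500 UMIs, an alternative chosen after seeing the data, the shares were 2.51% and 4.55%.

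**Figure D1:**
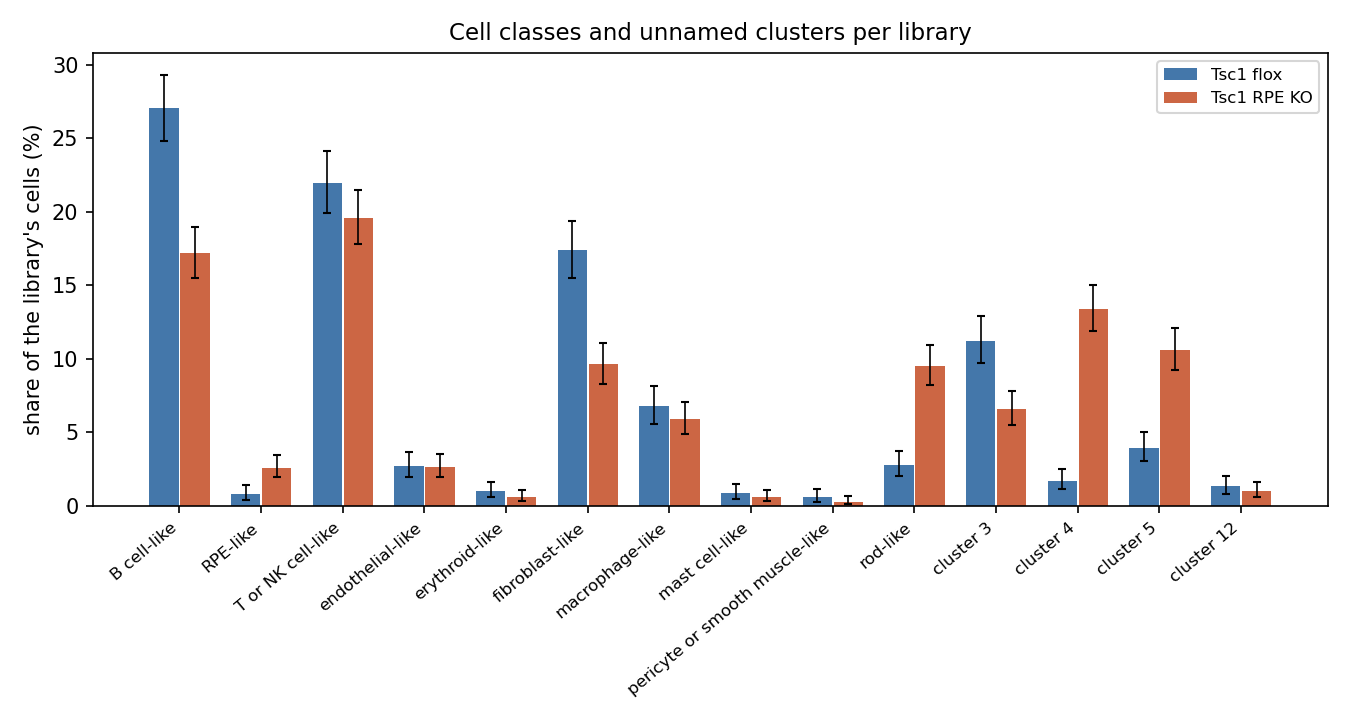
Share of each library's cells (%, vertical axis) in each named class and unnamed cluster (horizontal axis), with Tsc1 flox in blue and Tsc1 RPE KO in orange and exact 95% intervals as error bars. RPE-like cells stand at 0.787% and 2.59%, rod-like cells at 2.76% and 9.50%, and cluster 4 at 1.71% and 13.4%.

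Tsc1 itself (ENSMUSG00000026812, chromosome 2, 28641228 to 28691167, plus strand, mm10) had 0 UMIs in the RPE-like cells of either library, so no difference was detectable at this depth. From 32094 and 133784 UMIs in all, the exact Poisson upper limits were 115 CPM (counts per 1000000 UMIs) in Tsc1 flox and 27.6 CPM in Tsc1 RPE KO. Outside the RPE, Tsc1 was at 24.2 and 29.8 CPM in B cell-like cells and at 37.8 and 33.4 CPM in fibroblast-like cells of Tsc1 flox and Tsc1 RPE KO. Tags at the 3' end need not fall in the deleted part of the gene, so the level of Tsc1 checks nothing about the labels. Tsc2, chosen after its values were seen, also had 0 UMIs in both sets of RPE-like cells.

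Ppp1r1b (ENSMUSG00000061718, chromosome 11, 98348404 to 98357796, plus strand, mm10) encodes DARPP32, an inhibitor of protein phosphatase 1 that is regulated by phosphorylation. It had 0 UMIs in the 12 Tsc1 flox RPE-like cells and 29 UMIs in the 48 Tsc1 RPE KO cells, or 217 CPM (145 to 311). Against the floor of 3 counts over the Tsc1 flox cells its ratio was 2.32, with a lower interval bound of 1.77. Ppp1r1b was seen in 20 of the 48 Tsc1 RPE KO cells (41.7%, 27.6 to 56.8%) and in 0 of 12 Tsc1 flox cells, which at 3 counts of the total allows a share of up to 25% of cells with a UMI. This limits cells with a UMI, not cells that express the gene. No B cell-like, T or NK cell-like, fibroblast-like or macrophage-like cell of either library held a Ppp1r1b UMI, although their median depths, from 3866.5 to 9984 UMIs, lay above those of RPE-like cells, 2582 and 2250.5 UMIs. Rod-like cells had Ppp1r1b in 6 of 176 Tsc1 RPE KO cells (3.41%, 1.26 to 7.27%) and in 0 of 42 Tsc1 flox cells.

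Fewer UMIs per cell reduced what could be seen of Ppp1r1b. After thinning to 1000 UMIs per cell it was left in 8 of 48 Tsc1 RPE KO cells (16.7%, 7.48 to 30.2%) and 0 of 12 Tsc1 flox cells, a level at which the floor of the Tsc1 flox cells allows no fold. With at least 500 UMIs and without mixed barcodes, which raised the RPE-like cells to 42 and 92, Ppp1r1b had 2 and 34 UMIs, a ratio of 6.84 with a counting interval of 1.75 to 58.8. In RPE-like barcodes below the UMI minimum alone it had 2 and 10 UMIs, a ratio of 3.18 with an interval that included 1 (0.677 to 29.8).

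The median UMI count of RPE-like cells was 0.872 times as high in Tsc1 RPE KO as in Tsc1 flox. The same ratio was 0.990 in B cell-like, 0.900 in T or NK cell-like, 1.01 in fibroblast-like and 1.02 in macrophage-like cells. It turned to 1.09 with at least 1000 UMIs in both libraries, so no direction is given for the RPE.

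In the RPE-like cells, Elovl1 and Cox8b ranked highest among the genes that stood higher in Tsc1 RPE KO, and Rpe65 and Enpp2 ranked first among those that stood lower. Elovl1, an elongase of very long chain fatty acids, had 1 UMI in Tsc1 flox and 116 in Tsc1 RPE KO, a ratio of 27.8 (4.90 to 1108). Cox8b, a subunit of cytochrome c oxidase, was 5.37-fold higher (3.44 to 8.88), at 623 CPM in Tsc1 flox and 3349 in Tsc1 RPE KO, with 55% of its 20 Tsc1 flox UMIs in 1 cell. Rpe65, the isomerase that makes 11-cis-retinol, was 4.21-fold lower (3.44 to 5.15), at 6201 CPM in Tsc1 flox and 1473 in Tsc1 RPE KO. Rpe65, Rgr, Rrh and Lrat are also markers that named the cluster; clustering without the RPE markers and the ranked genes, an alternative added after seeing the data, gave 12 and 47 RPE-like cells.

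Among the 12 genes ranked highest, App, the amyloid precursor, was 3.53-fold higher (1.86 to 7.51) and Pcolce, an enhancer of procollagen processing, 3.76-fold (1.66 to 10.5). Psap, the precursor of the lysosomal saposins, was 2.09-fold higher (1.64 to 2.69), Gpx4, which reduces lipid peroxides, 1.65-fold (1.40 to 1.97) and Trf, transferrin, 1.502-fold (1.37 to 1.65). Lrat, which esterifies retinol, was 1.96-fold higher (1.28 to 3.13). The others were Zbtb20, Uqcrb, Ucp2 and Mgll, with ratios between 2.25 and 3.54. Elovl1 was seen in 39 of the 48 Tsc1 RPE KO cells, Cox8b in 44 and Psap in 46.

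Among the 12 genes ranked lowest, Enpp2, the secreted enzyme autotaxin, was 3.74-fold lower (2.91 to 4.81), Rgr, an opsin of the RPE, 2.57-fold lower (2.32 to 2.85) and Rrh, peropsin, 2.501-fold lower (1.61 to 3.84). Cspg5 was 3.05-fold lower (1.95 to 4.72), Pdpn 2.89-fold (1.70 to 4.84), Pltp, a phospholipid transfer protein, 2.63-fold (1.68 to 4.07) and Bsg, basigin, 1.91-fold (1.66 to 2.20). Cst3, cystatin C, was 1.70-fold lower (1.60 to 1.81), at 47361 CPM in Tsc1 flox and 27806 in Tsc1 RPE KO. Taldo1, Pon1 and Hsp90aa1 were between 2.03-fold and 2.34-fold lower. Overlapping genes on the same strand share the loci of Pcolce (Fbxo24) and Trf (Gm20425) in the annotation, so their counts are less certain.

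**Figure D2:**
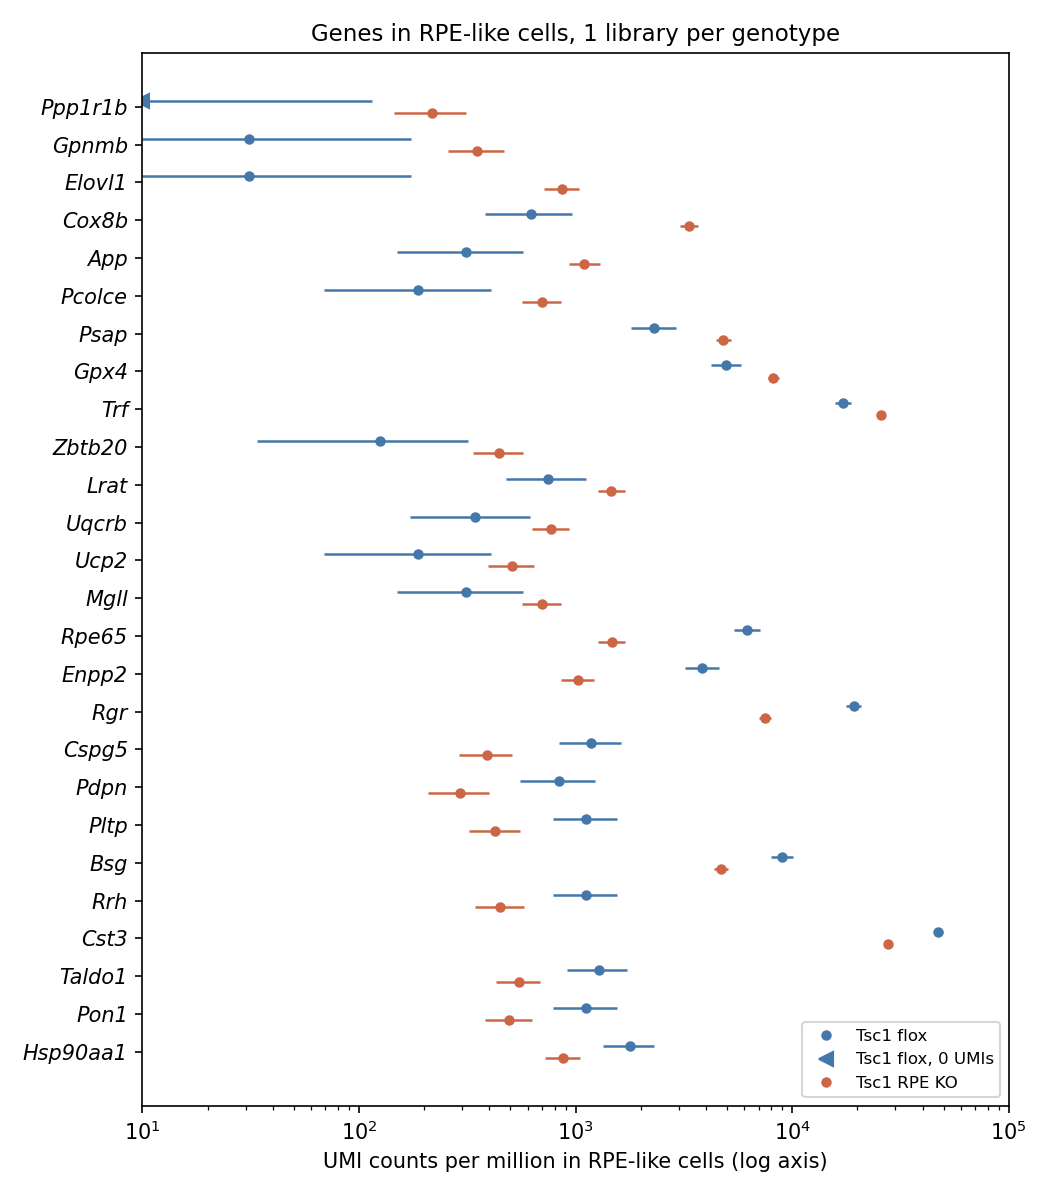
CPM in RPE-like cells (horizontal log axis) for Ppp1r1b, Gpnmb and the 24 ranked genes, as points with exact 95% Poisson intervals, for Tsc1 flox (blue, 12 cells) and Tsc1 RPE KO (orange, 48 cells); the triangle marks 0 UMIs. Elovl1 and Cox8b stand to the right in Tsc1 RPE KO, and Rpe65 stands at 6201 CPM in Tsc1 flox and 1473 in Tsc1 RPE KO.

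RNA of lymphocytes was present in part of the Tsc1 RPE KO set, and the limit used here to mark such barcodes was chosen after they had been seen. In 4 of its 48 RPE-like barcodes, which held 21.3% of its UMIs, there were 22 to 53 UMIs of immune cell markers, against at most 2 in each of the other 44 and in each of the 12 Tsc1 flox barcodes. These mixed barcodes had 127 UMIs of Cd74 and 199 of the immunoglobulin gene Igkc, and a median of 23.7% of their UMIs came from ribosomal protein genes, against 3.69% in the other Tsc1 RPE KO barcodes and 4.55% in Tsc1 flox. Scrublet had not marked them as doublets, and the Tsc1 RPE KO values above include them. Those with 9065 and 4736 UMIs held only 15 and 11 UMIs of Ttr, and those with 10006 and 4636 UMIs held 417 and 172. Without the 4 barcodes, all 12 of the higher and all 12 of the lower genes kept their direction and only the interval of Mgll came to include 1, while Ppp1r1b had 24 UMIs. For the 12 lower genes this was fixed, because losing 21.3% of the UMIs cannot raise a CPM enough to bring their intervals to 1. Several ratios moved outside their main intervals. Rpe65 was then 3.38-fold lower (2.76 to 4.15), Rgr 2.09-fold (1.89 to 2.32), Bsg 1.59-fold (1.37 to 1.83) and Cst3 1.43-fold (1.34 to 1.52). Trf was 1.84-fold higher (1.68 to 2.01). With at least 500 UMIs as well, several ratios lay nearer to 1. Elovl1 was then 18.4-fold higher (6.16 to 90.2), App 1.87-fold (1.36 to 2.63) and Zbtb20 2.08-fold (1.23 to 3.74), and the interval of Uqcrb, at 1.40, included 1. Cspg5 was 1.73-fold lower (1.23 to 2.42), Pdpn 1.68-fold (1.10 to 2.56) and Rrh 1.63-fold (1.18 to 2.24). In RPE-like barcodes below the UMI minimum alone, the ratio of App was 1.22 (0.803 to 1.88), and Cspg5 and Pdpn stood slightly higher in Tsc1 RPE KO, with intervals that included 1. Lrat at 1.10 (0.730 to 1.69), Rrh at 0.943 (0.586 to 1.54) and Bsg at 0.950 (0.786 to 1.15) also lost most of their difference there. Elovl1 was 10.8-fold higher (2.77 to 92.9) and Cox8b 2.36-fold (1.62 to 3.54). Pcolce and Zbtb20, each at 1.61 (0.827 to 3.34), and Gpnmb, at 2.44 (0.965 to 7.32), had intervals that included 1. Of the 24 ranked genes, 13 had intervals there that excluded 1 in the same direction.

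**Figure D3:**
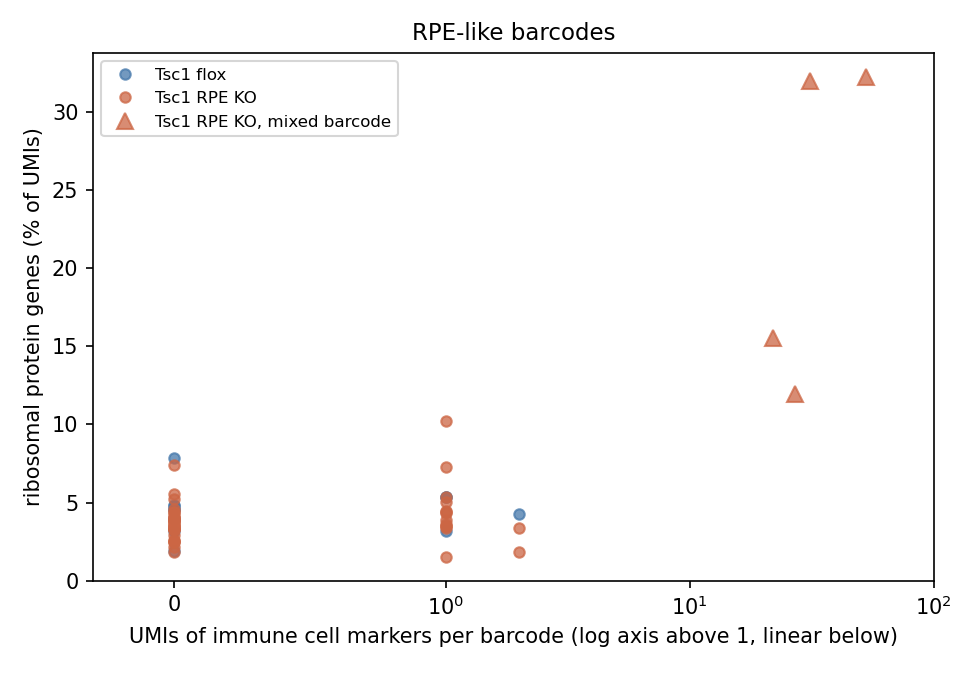
Each RPE-like barcode by its UMIs of immune cell markers (horizontal axis, log above 1) and the share of its UMIs from ribosomal protein genes (%, vertical axis), for Tsc1 flox (blue) and Tsc1 RPE KO (orange). The 4 mixed barcodes, drawn as triangles, have 22 to 53 marker UMIs and stand apart from all others, which have at most 2.

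Of the visual cycle and retinoid list, 9 of 10 measured members stood lower in Tsc1 RPE KO, 6 of them with intervals below 1, with a median log2 ratio of -0.50 at percentile 2.56 of random lists. Rdh10, a retinol dehydrogenase, was 1.84-fold lower (1.38 to 2.44), while Lrat went the other way. Without the mixed barcodes the median was -0.21 at percentile 17.1, with 6 members lower and 4 higher. With at least 500 UMIs as well it was -0.44 (-0.60 to -0.14) at percentile 1.04, but 4 members stood higher, all with intervals above 1, against 6 lower, 5 of them with intervals below 1. The list thus went both ways, and its place among random lists depended on the setting, while Rpe65, Rgr, Rrh and Rdh10 stayed below 1 with their intervals in each. Most of these genes also belong to the RPE markers.

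The mitochondrially encoded genes stood higher together. All 11 measured members were above 1, 10 of them with their intervals, and the median log2 ratio was 0.98 at percentile 99.9, with mt-Nd1 3.43-fold higher (1.81 to 7.31) and mt-Co2 2.31-fold (1.75 to 3.12). Without the mixed barcodes the median was 1.04, and with at least 500 UMIs as well mt-Nd1 was 2.13-fold higher (1.47 to 3.20). Free RNA of Tsc1 flox and Tsc1 RPE KO held more of these genes than the RPE-like cells did. There mt-Nd1 was at 1513 and 1748 CPM against 312 and 1069, and mt-Co2 at 5166 and 5873 against 1683 and 3894. With free RNA subtracted the median was 0.997. Differences in the preparation of the RPE were not separated from the genotype. In other classes the median of this list was -0.07 in B cell-like, -0.10 in T or NK cell-like, -0.02 in fibroblast-like and 0.02 in macrophage-like cells. The nuclear-encoded oxidative phosphorylation genes went both ways, with 24 of 54 higher and a median of -0.09 at percentile 14.6. With at least 500 UMIs and without mixed barcodes the sign turned, with 36 of 56 higher and a median of 0.11 (0.02 to 0.25) at percentile 98.1, so no direction is given for them. Ndufs3 had 0 UMIs in Tsc1 flox and 35 in Tsc1 RPE KO, a ratio of 2.80 against the floor with a lower interval bound of 2.16. Cox5a had 1 and 38, a ratio of 9.12 (1.54 to 369). Ndufc1 was 1.88-fold lower (1.21 to 2.88), with an interval that included 1 without the mixed barcodes.

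Of the lysosome list 4 of 5 measured members stood higher, with a median of 0.29 at percentile 73.2. Gpnmb, a lysosomal and melanosomal glycoprotein, had 1 UMI in Tsc1 flox and 47 in Tsc1 RPE KO, a ratio of 11.3 (1.93 to 455), or 3.85 (1.77 to 9.95) from 7 and 67 UMIs with at least 500 UMIs per cell and without mixed barcodes, and Ctsb, cathepsin B, was 1.83-fold higher (1.08 to 3.30). The median of the lysosome and autophagy list was 0.74 at percentile 99.3 with at least 1000 UMIs in both libraries. Without the mixed barcodes it was 0.61 at percentile 96.6, and with at least 500 UMIs as well 0.91 at percentile 99.99, with 6 of 6 members higher. The list thus stood apart from random lists only when cells below the main UMI minimum were included.

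Of the pigment genes, Dct, dopachrome tautomerase, was 2.06-fold higher (1.43 to 3.07), whereas Tyr, tyrosinase, had 8 UMIs in Tsc1 flox and 1 in Tsc1 RPE KO. The 8 came from 3 of 12 cells, with 37.5% in 1 of them. Tyr was 33.3-fold lower with a counting interval of 4.47 to 1480, or 11.9-fold (4.46 to 40.0) with at least 500 UMIs and without mixed barcodes. Rragd, a Rag GTPase that acts upstream of mTORC1, had 0 and 19 UMIs, a ratio of 1.52 against the floor with a lower interval bound of 1.12. No member of the mTORC1, DARPP32, mesenchymal, cholesterol or cell cycle lists reached 50 UMIs in RPE-like cells, nor did 3 members of the pigment, phagocytosis, ATF4 or immediate early lists, so these have no median. Insig1, a regulator of sterol synthesis, had 7 UMIs in Tsc1 flox and 9 in Tsc1 RPE KO, and Sqle, squalene epoxidase, had 3 and 1. The choroidal matrix and endothelial lists also had 0 measured members there. Ccnd1, cyclin D1, had 10 and 9 UMIs, at 312 and 67.3 CPM, and was 2.21-fold lower (1.05 to 4.59) with at least 500 UMIs and without mixed barcodes.

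All 5 measured junction and polarity genes stood lower, with a median of -0.46 at percentile 8.35, among them Bsg and Krt18, which was 1.74-fold lower (1.14 to 2.61). The list lay nearer to 0 without the mixed barcodes, at -0.24, and with at least 500 UMIs as well 2 of the 5 stood higher, with a median of -0.16 at percentile 36.3. Krt8 had 12 and 15 UMIs and was 3.33-fold lower (1.43 to 7.63), and Cdh3 had 5 and 3 UMIs. The medians of the glycolysis, antioxidant and unfolded protein response lists lay within the central 95% of random lists. They were -0.14 for glycolysis, where Eno1 was 1.89-fold lower (1.13 to 3.09) but 1.22-fold (0.781 to 1.88) with at least 500 UMIs and without mixed barcodes, -0.23 for antioxidant genes, where Mt1 was 1.41-fold lower (1.27 to 1.56), and -0.36 for the unfolded protein response, where Hsp90b1 was 1.82-fold lower (1.04 to 3.10) and Manf had 8 and 7 UMIs. In the same alternative the interval of Hsp90b1, at 1.51-fold lower (0.990 to 2.29), included 1, and the glycolysis and antioxidant medians changed sign over the alternatives.

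The ribosomal protein genes stood higher, with 68 of 74 measured members above 1 and a median of 0.85 at percentile 100. The same 4 mixed barcodes carried this difference: without them the median was -0.13 at percentile 29.8, with 22 of 51 members higher. Rps4x, 5.11-fold higher (2.42 to 12.9) with all barcodes, was at 1.48 (0.646 to 3.96) without them, and Rplp0 and Rpsa also came to have intervals that included 1. Immune genes behaved in the same way. Cd74 had 2 and 128 UMIs, of which 1 of the 128 lay outside the mixed barcodes, and H2-Aa and H2-Eb1 had 35 and 30 UMIs, each with 1 outside them. Jund, Junb and Ier2 had 54, 44 and 20 UMIs in Tsc1 RPE KO and 0 in Tsc1 flox, and 7, 2 and 1 outside the mixed barcodes. H2-D1 had 77 UMIs in Tsc1 RPE KO and 7 outside them, and H2-K1 33 and 9. These H2 genes are close relatives that can share reads. The list of complement and MHC class I genes had a median of -0.06 over 3 measured members, and that of macrophage activation -0.17 over 3. Over the alternatives these medians ran from -0.57 to 0.53 and from -0.17 to 1.14, with percentiles of 0.505 to 94.9 and 25.1 to 99.6, so no direction is given for either list.

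The other classes, in which the labels place no Cre, differed between the libraries as well. In macrophage-like cells, 13 of 14 measured members of the macrophage activation list stood higher in Tsc1 RPE KO, with a median of 0.75 (0.64 to 0.81) at percentile 100. The class is cluster 8 alone, led by F13a1, Fn1, Wfdc17, Lyz2 and Cd14. Its monocyte genes Ly6c2, at 1306 CPM, and Ccr2, at 518 CPM, were the highest of all clusters. C1qa was seen in 1 of 103 and 6 of 109 cells, so the class may hold mostly monocytes. A different mix of cells can set the differences of the class. The members named for this list and for those below were chosen after the lists had been ranked. Among them the MHC class II gene H2-Eb1 was 1.86-fold higher, in 36 of 103 and 50 of 109 cells, Apoe 1.74-fold with 32.4% of its Tsc1 RPE KO UMIs in 1 cell, and the chemokine gene Ccl3 3.76-fold with 60.7% in 1 cell. Retnla had 0 UMIs in Tsc1 flox and 149 in Tsc1 RPE KO, but 98.7% of these lay in 1 cell. Its ratio was 46.7 against the floor, with a lower interval bound of 37.5. C1qa and C1qc, complement genes of the macrophage marker list, were 28.8-fold (12.1 to 90.0) and 20.3-fold (8.45 to 63.9) higher, from 6 and 7 of 109 cells, with 39.2% and 34.3% of their Tsc1 RPE KO UMIs in 1 cell. Lyz1, which can share reads with its close relative Lyz2, was 35.9-fold higher (16.3 to 98.9), from 13 of 109 cells with 41.9% of the UMIs in 1 of them.

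The interferon-inducible chemokine gene Cxcl10 was 15.2-fold lower (8.03 to 32.4) in macrophage-like cells of Tsc1 RPE KO, with 56.6% of its Tsc1 flox UMIs in 1 cell. Chil3 was 2.80-fold lower (2.23 to 3.54), Ifit1bl1 4.35-fold (2.21 to 9.32; 35.6% of its Tsc1 flox UMIs in 1 cell) and Yae1d1 4.65-fold (2.67 to 8.57), the last with 80% of its Tsc1 flox UMIs in 1 cell. The immediate early list had a median of -0.20 (-0.26 to -0.11) at percentile 0.095, with 11 of 15 members lower, Fos among them. The cholesterol list had -0.23 at percentile 0.82, the lysosome list 0.16 at percentile 98.6 and the complement and MHC class I list 0.20 at percentile 98.7.

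In fibroblast-like cells the immediate early list went the opposite way, with 14 of 15 members higher and a median of 0.24 (0.15 to 0.31) at percentile 99.98, Atf3 being 2.02-fold higher. Of the choroidal matrix list 11 of 14 members stood lower, with a median of -0.18 (-0.26 to -0.07) at percentile 1.18, and Col1a1 was at 0.603 times its Tsc1 flox level. Angptl7 was 5.28-fold lower (3.38 to 8.65), with 54.1% of its Tsc1 flox UMIs in 1 cell. The basement membrane collagen gene Col15a1 was 4.13-fold lower (2.71 to 6.51), Klf11 3.53-fold (1.88 to 7.20) and the water channel gene Aqp1 3.28-fold (1.86 to 6.16). Smoc2 was 4.04-fold higher (3.07 to 5.37), Sfrp4 3.52-fold (2.61 to 4.79), Cav1 4.61-fold (2.42 to 9.39) and Gm12840 3.76-fold (2.40 to 6.05), and 1 cell gave 46.2%, 72.1% and 56.1% of the Tsc1 RPE KO UMIs of the first 3.

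In T or NK cell-like cells the interferon-inducible genes Ifi213 and Ifi206 were 14.7-fold (6.04 to 46.7) and 5.54-fold (3.89 to 8.09) higher in Tsc1 RPE KO, in 64 and 141 of 363 cells. The cytokine gene Il17a was 10.9-fold higher (7.38 to 16.7), but its 306 UMIs came from 3 cells. Tnfrsf4 was 3.41-fold higher (1.85 to 6.70), with 43.8% of its UMIs in 1 cell. The gamma delta T cell gene Tcrg-C1 was 3.24-fold lower (2.20 to 4.88), Krt83 3.52-fold (1.82 to 7.34), Myb 2.86-fold (1.49 to 5.86) and Ctla2b 2.68-fold (1.45 to 5.22). The cholesterol list had a median of 0.37 (0.13 to 0.57) at percentile 99.8, and 72 of 80 ribosomal protein genes stood lower by a median of -0.05. The class pools clusters 1 and 6 in different proportions, with 238 and 97 cells in Tsc1 flox and 229 and 134 in Tsc1 RPE KO, and this mix can set differences of the class.

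In B cell-like cells Ifi206 was 3.28-fold higher (2.13 to 5.18) in Tsc1 RPE KO, in 57 of 318 cells against 26 of 412, and Gdpd3 was 2.98-fold higher (2.08 to 4.35). The immunoglobulin genes Ighg2b and Ighg1 were higher from 5 and 2 cells. Ggta1 was 2.89-fold lower (1.67 to 5.27), E330020D12Rik 2.38-fold (1.57 to 3.69), Wfdc21 2.38-fold (1.48 to 3.95) and Eea1 2.02-fold (1.39 to 2.99). The glycolysis list had a median of 0.23 at percentile 99.8 with a counting interval that reached -0.02, and 63 of 80 ribosomal protein genes stood higher by a median of 0.08. Ifi206, Ifi213 and their neighbours form a family of similar genes, so reads can be shared among them.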

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

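Of the tests in this part, that of interferon-stimulated genes in T or NK cell-like cells was set before its result was seen. Values of some single interferon genes were already known at that point. The subtraction of free RNA was also set before its values were seen, but its use to weigh the results below was chosen afterwards. The other tests were chosen afterwards.

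Pltp, which encodes a phospholipid transfer protein, differed in direction between cell classes. It was 2.63-fold lower in RPE-like cells of Tsc1 RPE KO and 2.47-fold higher in macrophage-like cells, a difference between classes that was not tested. Pltp was also 2.82-fold higher in B cell-like cells (1.42 to 5.90). Other named genes also went opposite ways, such as Cst3 and Ccnd1, which were lower in RPE-like cells. In fibroblast-like cells they were 1.45-fold (1.37 to 1.53) and 3.84-fold (1.63 to 10.0) higher. Barcodes with 10 to 100 UMIs, which entered no comparison between cells, held more RNA of several marker lists in Tsc1 RPE KO. Rod markers were 2.23-fold higher (2.16 to 2.30), RPE markers 1.80-fold (1.70 to 1.91) and melanocyte markers 2.26-fold (1.73 to 2.99). Cone, macrophage, mast cell and Schwann cell markers were higher by 1.51-fold, 1.38-fold, 1.35-fold and 1.33-fold, with intervals above 1, while erythroid markers were 2.53-fold lower (2.503 to 2.56).

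The ribosomal protein list stood higher in Tsc1 RPE KO RPE-like cells, with a median log2 ratio of 0.85. Free RNA made up 1.34% and 1.66% of the RPE-like UMIs when all rod marker UMIs in them were counted as free RNA, and subtracting it left the median at 0.89, so free RNA of that profile is too small a share to account for it. Leaving out the 4 mixed barcodes brought it to percentile 29.8 of random lists. These barcodes were picked after being seen and had a median ribosomal share of 23.7%, so a fall was built in, though not its size. RNA of lymphocytes in the mixed barcodes may therefore account for this difference and for Cd74, H2-Aa, H2-Eb1, Junb and Ier2. Those with 9065 and 4736 UMIs had only 15 and 11 UMIs of Ttr, so they may be lymphocytes with little RPE RNA rather than RPE cells. Without the mixed barcodes, 5 of 51 ribosomal intervals lay below 1 and 0 above. With at least 500 UMIs as well, 10 of 71 lay below and 2 above. With 1 library per genotype, neither an effect of the genotype on ribosomal protein genes nor its absence can be shown.

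The 24 ranked genes of RPE-like cells, with Elovl1, Cox8b, Psap and Lrat higher and Rpe65, Enpp2 and Rgr lower, were weighed against 3 technical explanations. Without the mixed barcodes 23 of the 24 intervals still excluded 1 in the same direction. For the 12 lower genes this was fixed, because losing 21.3% of the Tsc1 RPE KO UMIs cannot raise a CPM enough to bring their intervals to 1. Of the 12 higher genes 11 kept such intervals, in barcodes that had also given the ranking. With the same small share of free RNA subtracted 24 of the 24 ratios stayed within their intervals, which adds little beyond the size of that share. Chance extremes picked by the ranking would give 12 of 24 genes the same direction in RPE-like barcodes below the UMI minimum, which had not entered the ranking; 21 of 24 did, in 30 Tsc1 flox and 48 Tsc1 RPE KO barcodes, with Uqcrb, Cspg5 and Pdpn as exceptions, and the interval of 13 of them excluded 1, while Lrat, Rrh and Bsg lay close to 1 there, although these barcodes came from the same 2 libraries. What stays open is the genotype, in which the loss of Tsc1 and the Best-Cre transgene cannot be told apart. Any difference between the 2 pools of mice, their genetic background or the preparation of their RPE also stays open, because 1 library per genotype cannot separate them.

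Genes near Ifi206 on chromosome 1 differed in several immune classes that the labels do not place under Cre. The region was found by scanning all genes, and its width and the criteria were set after that scan. Of 39 genes that differed at least 1.5-fold, with intervals that excluded 1, in the same direction in at least 2 of the 4 classes, 4 lay within a window of 5 Mb around Ifi206, against at most 2 in any other window of that width: Slamf7 and Ifi206 were higher in 3 classes, and Ifi214 and Ifi204 lower in 2. A general interferon response is argued against in B cell-like and macrophage-like cells, where Ifi206 was higher by 3.28-fold and from 2 to 51 UMIs while the interferon-stimulated genes lay at percentiles 0.615 and 0; in T or NK cell-like and fibroblast-like cells they lay at percentiles 99.7 and 99.6, so there it stays open, with 0 UMIs of Ifi206 in fibroblast-like cells. A candidate explanation is a haplotype, such as a strain variant, that differs between the mice of the 2 libraries, and shared reads among the similar Ifi genes could add to it, but sequence variants were not analysed here and this remains a hypothesis.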

How the results depend on the processing

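The 24 ranked RPE genes kept their direction under all 12 alternatives run on them; 255 of 288 ratios stayed within their counting intervals and 33 moved outside them. Leaving out the mitochondrial filter, keeping doublet calls and clustering at resolution 2 gave 12 and 48 RPE-like cells with 32094 and 133784 UMIs, as in the main setting. Their gene ratios could therefore not move, and these alternatives add no support to the counts above. Scaling by the median ratio, or by totals without mitochondrial and ribosomal protein genes, shifts every log2 ratio by the same constant. These shifts were too small to turn a ranked gene, as the smallest log2 ratio in size was 0.586, for Trf. Leaving out the mixed barcodes could not turn the 12 lower genes. Tsc1 stayed at 0 CPM in Tsc1 RPE KO throughout and at 0 to 33.2 CPM in Tsc1 flox. The few RPE-like cells of Tsc1 flox, 12 with 32094 UMIs, limit every comparison, and scaling by the median ratio moved the median log2 ratio of all genes from 0.09 to 0.30.

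With at least 1000 UMIs in both libraries, the RPE-like share of Tsc1 flox was 1.40%, the ratio of median UMIs 1.09, the ribosomal median 0.29 and the mitochondrially encoded median 0.63. The ribosomal median was 0.22 at resolution 0.5, 1.05 when scaled by the median ratio and 0.31 with equal weight per cell. Resolution 0.5 placed 46 Tsc1 RPE KO cells in the class instead of 48, with 119983 UMIs instead of 133784. That loss equals the UMIs of the mixed barcodes with 9065 and 4736 UMIs. Scaling by the median ratio moved all genes by the same constant, their median log2 ratio going from 0.09 to 0.30. Equal weight reduces the share of the deep mixed barcodes by construction. The cause of the shifts with at least 1000 UMIs was not tested. In thinned cells the ratio of Ppp1r1b against the floor was 0.833, below 1 because fewer UMIs raise the floor, and Ppp1r1b kept 0 UMIs in Tsc1 flox.

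Alternatives chosen after seeing the data had these values. With at least 500 UMIs in both libraries, the shares were 2.51% and 4.55%, the ratio of median UMIs 1.26, the ribosomal median 0.0880, the mitochondrially encoded median 0.68 and the log2 ratio of H2-D1 -0.46. Without mixed barcodes, the visual cycle median was -0.21, the ribosomal median -0.13 and H2-D1 -1.49; these barcodes held the lymphocyte RNA. With both changes, the shares were 2.51% and 4.501%, the ratio of median UMIs 1.26, the ribosomal median -0.0775, the mitochondrially encoded median 0.75 and H2-D1 -1.21. Genes with at most 3 UMIs in both libraries under an alternative, such as H2-Aa without mixed barcodes, have no ratio there. The visual cycle, ribosomal and mitochondrially encoded lists were picked as leading results after their values were seen. The percentile of the visual cycle list ran from 0.18 to 21.9 over the alternatives. Clustering without the RPE markers and the ranked genes left 12 and 47 RPE-like cells.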

Other observations

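Rod-like cells were 3.45 times as frequent in the Tsc1 RPE KO library and RPE-like cells 3.29 times. Unnamed clusters 4 and 5 were also more frequent there, 7.84 and 2.69 times, while endothelial-like cells, from the same choroid, had a share ratio of 0.983. Rod-like cells were also deeper in Tsc1 RPE KO, with a median of 2798 UMIs against 2074.5 in Tsc1 flox.

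Erythroid RNA went the other way. Erythroid markers were at 94398 CPM in free RNA of Tsc1 flox and 37314 CPM in Tsc1 RPE KO, and neutrophil markers at 198 and 77.1 CPM. B cell markers in free RNA were 1.46-fold lower in Tsc1 RPE KO and fibroblast markers 1.62-fold lower, as were the shares of these classes among cells. Mast cell markers in free RNA were 1.35-fold higher, although the share of mast cell-like cells was 0.696 times that in Tsc1 flox, from 13 and 11 cells. Macrophage markers in free RNA were 1.38-fold higher, and the share of the class had no fixed direction, at 0.870 times that in Tsc1 flox without cluster 4 and 2.28 times with it.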
